A study of Caenorhabditis elegans with 2 samples.

How the data were processed

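Peak lists of 1 chromatin immunoprecipitation experiment in Caenorhabditis elegans were analysed, from 2 biological replicates of whole young adults at 62.5 hours. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp and the tagged F33H1.4 protein was precipitated through its green fluorescent protein tag. Per the labels, the lists are on build ce11. Per the notes deposited with the lists, those of each replicate were derived from its own alignments and the series lists from the alignments of both, together with further inputs whose content the notes do not state. The aligner and the peak caller are not given in the sources used here. Chromosome lengths of WBcel235 were compared with the largest peak end on each chromosome, and none was exceeded.

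The deposited lists give for each peak a signal, a score and a −log10 q, all computed by the authors, and the unthresholded lists add a −log10 of the irreproducible discovery rate (IDR), per the values deposited. The deposited score ran from 830 upwards in the 4 thresholded lists, which matches an IDR of about 0.01. The deposited signal has no stated scale between lists, so it was used to rank and describe peaks within a list, and the correlation between replicates rests on ranks or logs. The authors' thresholded lists of each replicate were used for the comparison of replicates, and the series list made from both for all other tests. The unthresholded lists were used for the checks named below. Columns of the unthresholded lists without a stated content were not used. The replicates are called biological in the labels. No control library was analysed here.

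Genes and transcripts came from the Ensembl annotation of WBcel235 and sequence from the RefSeq genome of the same build. There were 19973 protein-coding genes on the nuclear chromosomes with 29314 distinct 5' ends. A promoter window ran from 1000 bp upstream to 200 bp downstream of a 5' end of any protein-coding transcript. A summit was put in the first class that applied, of promoter, coding exon, UTR, intron, non-coding gene or pseudogene, and intergenic. Coordinates are 1-based. Peaks were called shared when they overlapped by at least 1 bp.

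Shares of peaks have exact binomial 95% intervals, which cover counting error only. Overlap, promoter share, central share and non-coding classes were tested by permutation against 1000 random placements on the same chromosome, signal percentiles by 100000 permutations across peaks, chromosomes by exact binomial tests, gene lists by Fisher's exact test and words by exact McNemar tests. Under the 50% reciprocal rule the placements were still counted by a 1-bp overlap, which makes that test stricter. Word windows reached 50 bp to each side of a summit and were compared with a window of the same size centred 300 bp away, and the log2 odds used a pseudocount of 0.5. Benjamini-Hochberg adjustment was made over the 28 protein-coding lists, the non-coding classes, the 23 motifs or the 2080 words. The 28 lists, the motifs and the tests were fixed before the data were examined, and 15 genes stand in more than 1 list. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

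Genes were named by a rule fixed beforehand. It took F33H1.4, the nearest gene of the 25 strongest promoter peaks found in both replicates, 4 members of each list that passed and up to 2 of each other list by strongest promoter peak, the nearest gene of the 3 strongest peaks of each replicate alone, and that of the 5 strongest peaks outside promoters. The main tests were tested on simulated data. For gene lists, lists bound 3 times as often as other genes were called in 98.3% of cases and unchanged lists in 0.9%, over 100 simulations of 19973 genes. Each gene was drawn independently there, and all genes outside the changed lists at the same rate. That simulation therefore does not cover genes that share a peak or shares of bound genes that differ between chromosomes. For 6-base words, of which 2080 were tested, 100% of 4 words planted in 10% of windows were called. Other words that shared 5 bases in a row with a planted word were left out, and 0.149% of the rest were called. Both sides of that simulation were flanking windows, of different peaks. It therefore does not cover calls that come from the different G and C content of summits. For the promoter share, 5.5% of 200 simulations without an effect were called at a threshold of 0.05.

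Alternatives fixed beforehand were other overlap rules, the conservative list, the stronger 50% of each list, each replicate's own list in place of the series list (which stands for leaving the other replicate out), other promoter windows, other placements, assignment to the nearest 5' end, genes with a symbol as background, other distances to non-coding genes, and other word windows, backgrounds and lengths. Alternatives chosen after seeing the data collapsed overlapping peaks to the strongest, left out peaks with a q value above 0.1, kept autosomal genes alone, or left out peaks near small RNA genes.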

Results

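Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the protein encoded by F33H1.4 sat on the genome of Caenorhabditis elegans. F33H1.4 is annotated as a protein with a C2H2 zinc finger domain, a fold that often binds DNA. The animals carried the gene fused to a green fluorescent protein tag, per the labels, and the tag was the target of the antibody. Whole young adults were collected at 62.5 hours. The series held 1 group of 2 biological replicates and no second condition, so the comparisons were between replicates, and between the peaks and the rest of the genome. The deposited lists held 2219 peaks for replicate 1, 2733 for replicate 2 and 3250 for the list made from both, called the series list here, with a companion of 3165 peaks that the authors call conservative and that has the same lowest score. Read depth per library is unknown from these lists. Replicate 2 had more thresholded peaks and replicate 1 more unthresholded regions (33529 against 30974), so the numbers do not rank the libraries. Peak signal is the authors' own value for each peak and was used to rank peaks within a list. Peaks and genes are not replicates, and p-values over them describe these lists.

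The peak at F33H1.4 itself lay in its own promoter. On chromosome II it spanned 10174417 to 10174713 (build ce11, the same as WBcel235), and its summit was 84 bp upstream of the annotated 5' end of the gene, which runs from 10174648 to 10180040 on the plus strand. Its signal was 504.3, rank 686 of 3250 in the series list. Each replicate's own list held the peak too, with a signal of 181 in replicate 1 and 329.7 in replicate 2. No thresholded list held a summit in the body of the gene, though in each of them the promoter peak reached past the annotated 5' end. The labels call the animals transgenic, and further copies of this region in a transgene could add reads here, which was not tested.

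The 25 strongest promoter peaks found in both replicates had signals between 2989 and 10451. The first was on chromosome IV at 1094105 to 1094605, with a signal of 10451 and rank 1 in both replicates (4478 and 6009.8). Its nearest 5' end belonged to Y55F3AR.2, and the same summit lay in the promoter window of cct-8, a subunit of the cytosolic chaperonin. The next were cap-2, an actin capping protein subunit (chromosome II, 10868729 to 10869228, signal 7149.9), lin-53, a histone-binding protein of the RbAp48 family (chromosome I, 9619753 to 9620241, signal 7044), Y25C1A.8 (chromosome II, 3076870 to 3077373, signal 6178) and lin-9, a subunit of the DREAM complex (chromosome III, 8903982 to 8904521, signal 6034). Signals between 3000.4 and 4357 were found at sgo-1, a shugoshin, hat-1, a histone acetyltransferase, sco-1, a cytochrome c oxidase assembly factor, hcp-4, the centromere protein CENP-C, and rpn-3, a proteasome subunit. The same range held mig-5, a Dishevelled protein, eel-1, a ubiquitin ligase, sqd-1, mex-1, a maternal RNA-binding protein, rbc-2, npp-3, a nuclear pore protein, and F22D6.8. It also held wapl-1, a cohesin release factor, ant-1.1, the mitochondrial ADP/ATP carrier, klp-18, a kinesin of the oocyte spindle, ndub-8, W08E12.7, rpl-29 and rpl-38. The last of the 25 promoter peaks chosen by strength, at C17E4.6, had a signal of 2989. Of the 25 summits, 24 lay upstream of the nearest 5' end and that of F22D6.8 lay 108 bp downstream. The strongest peaks outside promoter windows were nearest to F22D6.8 (a UTR, 1178 bp downstream of the 5' end, signal 4279.8), jmjd-2 (intergenic, signal 3382), pals-1 (an intron, signal 3339), C44B9.2 (an intron, signal 2774) and hmg-1.1 (intergenic, signal 2243).

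The comparison of the replicates asked how far the peaks of one recurred in the other. Replicate 2 peaks overlapped 1940 of the 2219 replicate 1 peaks by at least 1 bp (87.4%, 95% exact interval 86% to 88.8%). In the other direction 1952 of 2733 replicate 2 peaks were overlapped (71.4%, 69.7% to 73.1%). Random placement of the peaks on their own chromosomes gave 1.91% and 1.57% on average (one-sided permutation p = 0.000999 for each, the smallest that 1000 placements can give). Placement in promoter windows gave 4.98% and 4.12%, with the same permutation p of 0.000999. Signal in the 1940 shared pairs was a median 1.43 times as high in the list of replicate 2, whose scale is not known to be the same. Across these pairs, Spearman's rho of the signal was 0.924 and Pearson's r of log2 signal was 0.921, a description across peaks. Peaks found in 1 list alone sat low in it: their median signal percentile was 12.4 against 56.3 for shared peaks in replicate 1, and 19.9 against 64.3 in replicate 2 (two-sided permutation p = 1e-05 for each, the smallest that 100000 resamples can give). The strongest peaks of replicate 1 alone were nearest to ari-1.4 (signal 289.8), let-23, the epidermal growth factor receptor (125), and Y48C3A.20 (119.6). Those of replicate 2 alone were nearest to elli-1 (332), R151.1 (179.7) and lrpr-1 (177). Of all peaks found in 1 list alone, the other replicate's unthresholded list overlapped 240 of 279 for replicate 1 and 699 of 781 for replicate 2. Among the named ones it overlapped those near let-23 and R151.1, and not those near ari-1.4, Y48C3A.20, elli-1 and lrpr-1. The unthresholded lists covered 10028.5 kb for replicate 1 and 10025 kb for replicate 2. The overlap that random placement would give with them was not computed. In the series list, 1954 of 3250 peaks (60.1%) were overlapped by a peak of both replicates, 814 by a peak of 1 replicate alone and 482 by neither. The conservative list overlapped 2849 of the 3250 peaks of the series list and held 304 peaks that the series list did not overlap. The ratio of peak numbers was 1.23 between the replicates and 1.03 between the series lists.

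**Figure D1:**
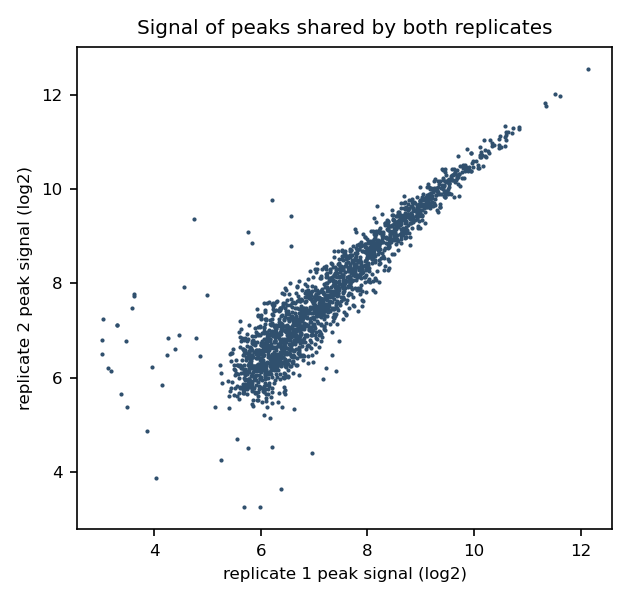
Signal of the 1940 peak pairs shared by the replicates, replicate 1 on the x axis and replicate 2 on the y axis, both as log2 of the authors' signal; each point is 1 pair. Most points lie along 1 band and scattered pairs lie far off it at low signal, with a Spearman's rho of 0.924 over all pairs.

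Promoters held most summits. Of 3250 summits, 2030 (62.5%, 95% exact interval 60.8% to 64.1%) lay between 1000 bp upstream and 200 bp downstream of the 5' end of a protein-coding transcript, against 26.3% of random placements (two-sided permutation p = 0.002, the smallest that 1000 placements can give). Coding exons held 2.58% of summits against 19.4% of placements, introns 14.1% against 28.5%, and intergenic sequence 15.2% against 19.9% (adjusted permutation p = 0.003 for each). UTRs outside promoter windows held 2.83% against 2.69% (adjusted permutation p = 0.625), and non-coding genes or pseudogenes 2.77% against 3.17% (adjusted permutation p = 0.249). The median promoter summit lay 185 bp upstream of the nearest 5' end, and 89.3% were upstream. Promoter windows of 2 or more genes shared 744 of the 2030 promoter peaks, so a peak cannot always be given to 1 gene. Promoter peaks were stronger than the others, with a median signal percentile of 60.7 against 35.0 (two-sided permutation p = 1e-05). Of the 325 strongest peaks 84.9% had the summit in a promoter window, and of the 325 weakest 36.6%.

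**Figure D2:**
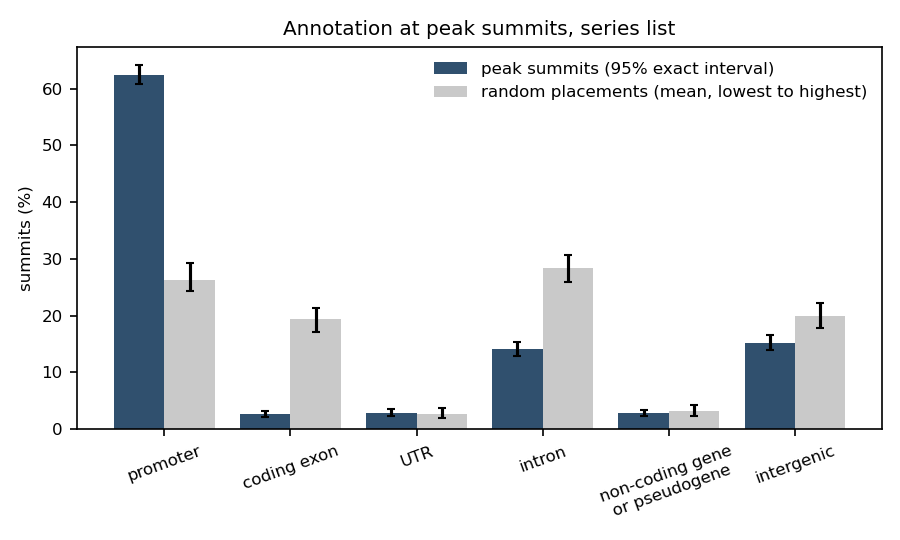
Share of the 3250 summits of the series list in each class of annotation (dark bars, 95% exact interval) and of random placements on the same chromosomes (light bars, mean with the lowest and highest of 1000 placements), in percent. Promoters held 62.5% of summits against 26.3% of placements, and coding exons 2.58% against 19.4%.

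The X chromosome held few peaks. It carried 93 peaks, 5.25 per Mb (95% Poisson interval 4.24 to 6.43), while chromosome III carried 54 per Mb, chromosome I 49, chromosome II 38.3, chromosome IV 36.4 and chromosome V 21.6. The density on the X was 0.137 times that of the autosomes (0.110 to 0.169), and the X held 2.86% of the peaks against 17.7% of the genome's length (two-sided exact binomial p = 4.66e-155) and 13.7% of protein-coding genes (two-sided exact binomial p = 2.18e-100). Of the 2731 genes on the X, 43 had a promoter peak (1.57%), against 603 of 2640 on chromosome III (22.8%) and 361 of 4994 on chromosome V (7.23%). The replicates had 46 and 64 peaks on the X. In the stronger 50% of the list the ratio fell to 0.0728. When each chromosome was divided into 3 sections of equal length, the central sections held 37.1% of summits against 33.3% of placements (two-sided permutation p = 0.002). They also held 37.8% of protein-coding 5' ends, and the share of summits did not differ from that (two-sided exact binomial p = 0.437). Genes with a promoter peak lay there more often than genes without, at 42.4% against 37.1% (two-sided Fisher's exact p = 2.68e-07). This test pooled the chromosomes, so the difference may come from which chromosomes held the genes with a peak.

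**Figure D3:**
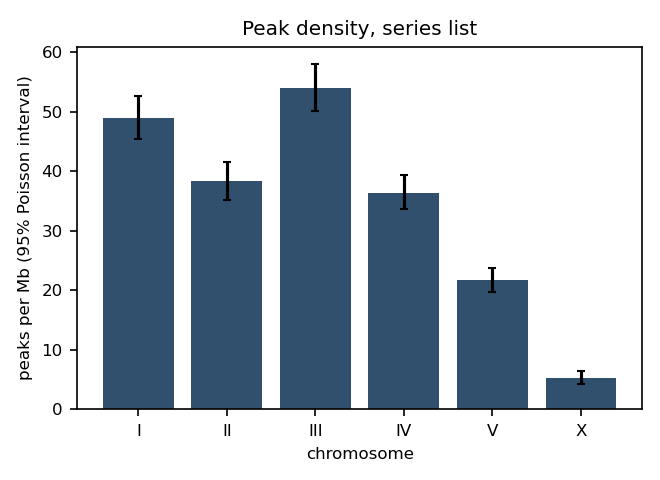
Peaks per Mb of the series list on each nuclear chromosome, with 95% Poisson intervals. The X stood at 5.25 per Mb, and the autosomes between 21.6 and 54.

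Ribosomal protein, germline, meiosis and cell cycle genes had the highest shares of bound genes among the 28 lists. A promoter peak was found at 2547 of 19973 protein-coding genes (12.8%). Ribosomal protein genes had one in 75 of 79 cases, among them rpl-29 (signal 3207), rpl-38 (3000.4), rps-0 (2763) and rpl-41.2 (2704). Germline and oocyte genes had one in 40 of 47, with mex-1 (3665), puf-3 (2341, an RNA-binding protein of the Pumilio family), egg-1 (2334, an oocyte surface protein) and mex-5 (2172) the strongest. For meiosis genes the count was 26 of 33, led by the cohesin subunits coh-3 (2879), coh-4 (2827) and rec-8 (2172) and by dsb-2 (1652), which acts in meiotic double-strand breaks. The summit at rec-8 was also that of mex-5. Cell cycle and DNA replication genes had a peak in 34 of 46 cases, led by hcp-4 (4009), rpa-2 (2313), rnr-1 (1982, ribonucleotide reductase) and rpa-1 (1919). All 4 groups were bound more often than other genes, with adjusted p = 7.91e-61, 3.00e-28, 4.80e-17 and 1.82e-20 in that order (two-sided Fisher's exact test, Benjamini-Hochberg over 28 lists). When each peak was given only to its nearest 5' end, ribosomal protein genes fell to 44 of 79 (55.7%), below germline (74.5%) and meiosis genes (63.6%), and still passed (adjusted exact p = 1.45e-24). No control library was analysed, so strong transcription or open chromatin cannot be told apart from binding of the protein at these genes. That limit holds for all gene lists here and below.

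Housekeeping complexes followed at lower shares. Translation factors had a promoter peak in 24 of 41 cases, led by eef-1A.1 (2988), eif-3.C (1143), eef-1B.1 (932) and eif-2gamma (910.0). Proteasome subunits had one in 19 of 33, led by rpn-3 (3922), rpn-5 (1193), rpn-6.2 (1091) and rpn-1 (832). Chromatin regulators of the synMuv class, which oppose vulval fate, had one in 15 of 27, led by lin-53, lin-9, lin-38 (1193) and lin-54 (1056). For the respiratory chain and ATP synthase the count was 32 of 66, led by ndua-8 (3659.7, the summit also assigned to rbc-2), ndub-8 (3256), ucr-1 (1627) and atp-2 (1582). Splicing and mRNA processing genes reached 28 of 59, led by pabp-2 (2989, the summit also nearest to C17E4.6), hrpa-1 (2006), rnp-8 (1952) and rsp-5 (1816). Heat shock proteins and chaperonins reached 26 of 59, led by cct-8, hsp-110 (3922, the summit of rpn-3), cct-1 (3902, the summit of mig-5) and hsp-6 (1623). The adjusted p in the same exact test lay between 7.87e-12 for the respiratory chain and 2.94e-07 for the synMuv class. With the nearest 5' end only, the heat shock and chaperonin list fell to 9 of 59 and no longer passed (adjusted exact p = 0.182), while splicing genes (18 of 59) and the synMuv class (10 of 27) fell and still passed. Histones had a peak in 17 of 72 cases, with his-67 and his-68 (530.2, a shared summit), his-74 (422) and his-42 (198) the strongest, and an adjusted exact p of 0.019. That call did not hold in either replicate's own list (adjusted exact p = 0.0507 in replicate 1 and 0.922 in replicate 2).

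Chemoreceptors, nuclear hormone receptors, F-box genes, C-type lectins and collagens were bound less often than other genes. Chemoreceptor genes had a promoter peak in 13 of 1309 cases (adjusted exact p = 1.91e-59), with srw-90 (338), sri-5 (318), srh-16 (300.3) and sre-40 (169.7) the strongest. Nuclear hormone receptors had one in 6 of 269, led by nhr-86 (1102), nhr-47 (485), nhr-247 (266) and nhr-142 (254), F-box genes in 10 of 322, led by fbxc-44 (1329), fbxc-45 (515), fbxb-85 (450.5) and fbxc-43 (374), and C-type lectins in 7 of 240, led by clec-88 (1619.7), clec-91 (612), clec-104 (326) and clec-87 (224). Collagens had one in 5 of 156, led by col-38 (471), col-111 (291), col-157 (264) and col-63 (197). These 5 families stayed below the other genes in each replicate's list, with chemoreceptors at 7 of 1309 and F-box genes at 6 of 322 in that of replicate 1. UDP-glucuronosyltransferases (2 of 67, ugt-12 at 1149 and ugt-40 at 241, adjusted exact p = 0.0173), epidermal and molting genes (1 of 46, scm-1 at 2488, adjusted exact p = 0.0394) and major sperm proteins (0 of 31, an exact interval up to 11.2%, adjusted exact p = 0.0403) passed more narrowly. The epidermal and sperm protein calls held in neither replicate's own list, and the glucuronosyltransferase call was lost in that of replicate 1 (adjusted exact p = 0.0977).

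The other 9 lists did not pass. Cytochrome P450 genes had a promoter peak in 4 of 74 cases (cyp-31A3 at 1739 and cyp-31A2 at 755, adjusted exact p = 0.0774) and homeobox genes in 6 of 63 (ceh-38 at 995, ceh-100 at 501.2). Tissue lists were low in number: 1 of 36 body wall muscle genes (act-2 at 287, adjusted exact p = 0.106), 0 of 20 pharynx genes (adjusted exact p = 0.121), 2 of 50 intestinal genes (end-3 at 115 and fat-6 at 71.1, adjusted exact p = 0.108), 4 of 51 neuronal genes (unc-11 at 2083 and unc-33 at 845) and 0 of 6 vitellogenins. Stress and longevity regulators had one in 8 of 48 cases (atfs-1 at 1447 and daf-18 at 806), and genes of the Notch, Wnt, TGF-beta and Ras pathways in 6 of 48 (pop-1 at 1127 and mom-2 at 723). These counts were 4 and 3 in the list of replicate 1, and 7 and 5 in that of replicate 2. In the conservative list cytochrome P450 and intestinal genes did pass, below the other genes (adjusted exact p = 0.0337 and 0.0285).

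**Figure D4:**
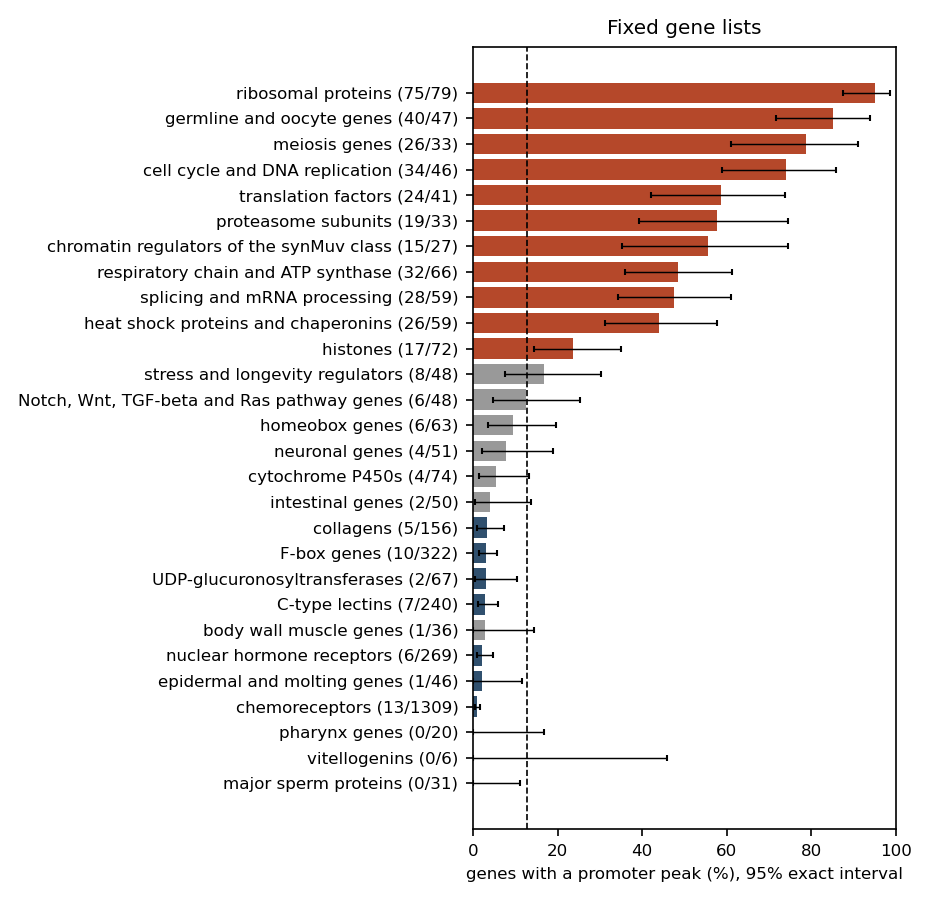
Percent of the genes of each fixed list with a promoter peak in the series list, with 95% exact intervals; counts stand beside the names. Red bars passed the test above other genes, blue bars below, grey bars did not pass, and the dashed line marks 12.8% of all protein-coding genes.

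Genes for small structural RNAs lay next to many summits. Within 200 bp of a tRNA gene there were 153 summits against 6.57 in the mean of random placements, within 200 bp of an snRNA gene 51 against 2.28, and within 200 bp of an snoRNA gene 96 against 6.66 (adjusted permutation p = 0.0032 for each, from the smallest p that 1000 placements can give). For tRNA genes the size of the difference moved with the list and the distance, from 23.3 times the mean of placements to 13.9 in the list of replicate 1, 8.35 in the stronger 50% of the series list, 11.4 within 500 bp and 93.0 for summits inside the gene. Within 500 bp it fell to 8.77 times for snoRNA genes and 11.7 for snRNA genes. Fewer summits than placed ones lay near piRNA genes (31, or 0.261 times the mean of placements) and pseudogenes (70, or 0.572 times), with the same adjusted permutation p. MicroRNA genes (7 against 3.46), long non-coding RNA genes (22 against 15) and rRNA genes (0 against 0.582) did not pass (adjusted permutation p = 0.148, 0.125 and 1). Against placements in promoter windows of the same chromosomes the pseudogene count was 1.08 times the mean, so that difference ended there, while long non-coding RNA genes passed (1.81 times, adjusted permutation p = 0.0288). MicroRNA genes passed in the conservative list, in the list of replicate 1 and within 500 bp (2.65, 2.85 and 1.87 times, adjusted permutation p = 0.0107, 0.0426 and 0.0457). Long non-coding RNA genes also passed within 500 bp (1.72 times, adjusted permutation p = 0.0032).

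Summits carried recurrent DNA words. GAGACC lay within 50 bp of 27.4% of summits and in 4.62% of flanking windows, a log2 odds of 3.49, and GGCGCA in 19.9% and 2.09%, a log2 odds of 3.75 (two-sided exact McNemar test, adjusted p = 4.12e-156 and 4.93e-128 over 2080 words). These were the words with the smallest p, so they were chosen after values were seen. Of 8-base words, AAAGGCGC was found at 13.4% of summits against 0.769% of flanks and GCGAGACC at 12.8% against 1.08%. Around 694 isolated copies of GAGACC nearest to a summit, the bases shared by at least 50% of copies read TCGNGGCGAGACCC, and around 464 isolated copies of AAGGCGC they read TTAAAGGCGCA. In 139 of the 890 peaks with GAGACC, 3 or more copies lay within 150 bp of the summit, and 93.0% of neighbouring copies were 15 or 30 bp apart. GAGACC was found at 62.5% of the 325 strongest summits and at 12.3% of the 325 weakest, and GGCGCA at 36.0% and 5.23%. Of the 23 motifs fixed beforehand, 7 were more frequent at summits and 8 less. The CGCG core was found at 45.4% of summits against 11.7% of flanks, the E2F-like site at 16.1% against 4.55%, the GACGC-containing element at 5.26% against 0.677% and the tRNA B box at 3.02% against 0.677%, with the GC box and the GAGA repeat also above flanks. For the tRNA B box the log2 odds fell from 2.29 to 1.05 in the list of replicate 1, and it no longer passed against promoters of unbound genes (adjusted exact p = 0.124). The general E-box (32.0% against 29.3%) passed in the series list, and not in the list of replicate 2, in the stronger 50% or against promoters of unbound genes (adjusted exact p = 0.338, 0.461 and 0.217). GATA sites (9.2% against 19.6%), the homeodomain core (2.18% against 5.32%) and T blocks (28.0% against 39.9%) were less frequent at summits, as were the Notch effector site and, with calls that did not hold throughout, 4 others. Of these the heat shock element was lost in both replicates' lists (adjusted exact p = 0.573 and 0.25), the forkhead site in that of replicate 2 (adjusted exact p = 0.386), the CCAAT box in that of replicate 1 and in the conservative list (adjusted exact p = 0.0781 and 0.117), and the Sox core with overlapping peaks collapsed (adjusted exact p = 0.0885). With windows of 100 bp on each side T blocks turned to more frequent (log2 odds 0.19, adjusted exact p = 0.0291). In all, 583 words were more frequent and 578 less, and summit windows had 45.1% G and C against 36.3% in flanks. That difference alone could raise words and motifs rich in G and C and lower those rich in A and T. Only GAGACC was tested in pairs without it, so for the motifs and other words base composition stays open.

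**Figure D5:**
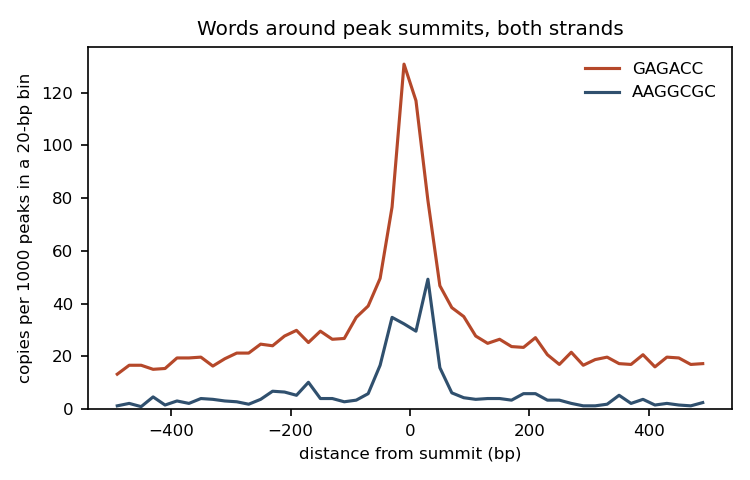
Copies of GAGACC and AAGGCGC on either strand per 1000 peaks, in bins of 20 bp from the summit of each of the 3250 peaks of the series list. GAGACC rose to 131 copies per 1000 peaks in the bin just left of the summit.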

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

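All tests of explanations in this part were chosen after the patterns they bear on had been seen, and the values that would exclude an explanation were set before its test was run only for identical tRNA copies, the gene content of the X and arrays of other units. The unthresholded series list held 82 peaks with the score of the thresholded list that are absent from it. They were noticed in data the comparisons above do not use. Of these, 74 were intergenic and 14 lay on the X. The strongest, on chromosome X at 15810932 to 15811190 in intergenic sequence, had a signal of 3043.7, and 1 in the promoter of rde-4 had a signal of 951. These genes were chosen after their values were seen, and the reason for the removal was not tested.

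Summits near tRNA genes were 23.3 times as frequent as in random placements, and 13.9 times in the list of replicate 1. Of tRNA genes whose whole sequence occurs once in the genome, 23.6% (33 of 140, 95% exact interval 16.8% to 31.5%) had a summit within 200 bp, against 1.14% in placements. That argues against reads shared between fully identical copies as the whole cause. Reads shared between copies that differ at few bases stay open, as does a summit that belongs to a neighbouring tRNA gene. Nearby protein-coding promoters do not account for the count, since it was 22.3 times the mean of placements in promoter windows. Strong transcription or open chromatin may contribute and cannot be told apart from binding of the protein here: 94.9% of ribosomal protein genes but 2.62% of 229 genes in 4 tissue-limited lists had a promoter peak, genes of few cells give little material from whole animals, and no control library was analysed here. No biological explanation was tested.

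The X held 0.137 times the density of peaks of the autosomes. GCGAGACC or AAAGGCGC lay in the promoters of 1.54% of X genes and 4.81% of autosomal genes. Autosomal genes with the same words gave an expected 12.9% of X genes with a promoter peak, against 1.57% observed (95% exact interval 1.14% to 2.12%). Autosomal genes without a word had a peak in 12.2% of cases, so that expectation could hardly have come out low and decides nothing. Among genes with a word, 28.6% of 42 on the X had a peak, against 60.6% of 829 on autosomes. Among genes without one, 1.15% on the X had a peak, against 12.2% on autosomes. The deficit was present in both groups and was proportionally larger without a word. The words were chosen from these same peaks, most of them autosomal, which may raise the autosomal share. Gene content was tested in the 11 lists bound more often, where 6 of 28 X members had a promoter peak and 14.6 were expected from autosomal members of the same lists (one-sided permutation p = 0.00063). These lists were chosen by the same peaks and have 534 autosomal members, so the choice may have raised the expected number. The 28 members do not stand for all genes of the X, so gene content outside these lists stays open. Lower coverage as the whole cause was predicted to thin weak regions as much, but regions that failed the IDR limit had a ratio of 0.679 (0.661 to 0.698). Of the 51479 regions in the unthresholded series list, 45842 had a q value above 0.1. Many may therefore be background, whose density need not follow coverage as that of peaks does. As the ratio is also itself below 1, this comparison does not decide and coverage stays open. A difference in X chromatin may contribute and was not tested.

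GAGACC lay at 27.4% of summits against 4.62% of flanks, and in the 2624 window pairs left after dropping every pair with a soft-masked, tandem or multi-copy occurrence, the log2 odds was 2.78 (two-sided exact McNemar p = 4.06e-46), which argues against repeats as the whole source for isolated copies. Arrays of 3 or more copies had a summit within 150 bp in 48.9% of 272 cases, and arrays of other 15-bp units in 10.5% of 162 (95% exact interval 6.23% to 16.3%), above the 1.37% of placements but far below the arrays of the word. The word had been chosen by its p at these summits, but in a test added afterwards, of the 3087 pairs with no such array near, it also ranked 1 of 2080 by p (log2 odds 3.38), so its choice did not rest on the arrays, and a mapping problem of this unit alone stays open. That 0 of 87 other words of the same bases reached its log2 odds of 3.49 (highest 2.58) decided nothing, as the word was chosen for its smallest p. In pairs whose summit window had no more G and C than its flank, tested after that, the log2 odds was 2.01 (two-sided exact McNemar p = 5.74e-18). Those pairs are among the ones by which the word was chosen, so that choice may have raised the value. The rank of the word among other words was not computed there. Direct recognition of this word by the F33H1.4 protein is a hypothesis that these lists cannot separate from binding through a partner.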

How the results depend on the processing

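The tests on collapsed peaks, weak peaks, autosomes and small RNA genes were chosen after seeing the data. The promoter share, the deficit on the X, the stronger signal of promoter peaks and the replicate overlap kept their direction and their side of the threshold under every alternative run. The central share did so against random placements in every list used, but not against protein-coding 5' ends, with 37.1% of summits and 37.8% of ends. Without either replicate, the promoter share ranged from 67.3% to 68.3%, the X ratio from 0.0986 to 0.112, the central share from 37.8% to 38.6% and the signal difference from 23.3 to 24.0 percentiles. The correlation between replicates moved from 0.924 to 0.946 with 50% reciprocal overlap, 0.939 with summits within 100 bp and 0.944 in the stronger 50% of each list; the cause was not tested. Lists bound less often numbered 8, and 5 to 6 in the replicates' own lists and 5 with the nearest 5' end only, where fewer bound genes were tested, and rose to 10 in the conservative list and 11 among genes with a symbol. Non-coding classes above placements rose from 3 to 5 at 500 bp, and those below fell from 2 to 1 against promoter placements, where pseudogenes turned to 1.08 times the mean (adjusted permutation p = 0.614); the cause was not tested. Enriched words rose from 583 to 1245 with 8-base words, of which more exist. With 100 bp on each side, general E-boxes turned to a log2 odds of -0.13 and T blocks to 0.19; the cause was not tested. Among single lists, 23 comparisons lost a call and 7 gained one, and among single motifs 16 lost and 5 gained one. Depth per library is unknown, so peaks missing from a list are not shown to be absent.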

Other observations

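All tests in this part were chosen after the data were seen. Nuclear pore proteins had a promoter peak in 18 of 26 cases (adjusted p = 4.24e-10, two-sided Fisher's exact test, Benjamini-Hochberg over these 10 groups), led by npp-3 (signal 3539), npp-9 (833) and npp-18 (743). Mitochondrial ribosomal proteins had one in 27 of 70 (adjusted exact p = 2.19e-07), led by mrps-21 (1949.6), with 17 in the list of replicate 1 and 25 in that of replicate 2. Exosome and deadenylation complex subunits had one in 8 of 14, kinesin-like proteins in 8 of 17, with klp-18 (3308) and bmk-1 (2879, the summit of coh-3) the strongest, and Argonautes in 8 of 20, with wago-4 (1643) the strongest. RNA polymerase, Mediator and TFIID subunits had one in 18 of 59, led by taf-4 (1859), aminoacyl-tRNA synthetases in 10 of 32, led by fars-1 (1129), and vacuolar ATPase subunits in 6 of 20, led by vha-8 (1028). The adjusted exact p of these 6 groups lay between 0.000203 and 0.0339. Neuropeptide receptors had a promoter peak in 0 of 84 cases (adjusted exact p = 5.01e-05) and ion channel genes in 3 of 141 (adjusted exact p = 3.79e-05). The ion channel count was 1 in the list of replicate 1 and 3 in that of replicate 2.

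GAGACC and AAGGCGC were less frequent at summits near small RNA genes than at other summits. GAGACC was found at 12.4% of summits near tRNA genes against 28.1% of the others, at 7.29% near snoRNA genes against 28.0% and at 3.92% near snRNA genes against 27.8% (adjusted p = 2.03e-05, 6.39e-06 and 4.48e-05, two-sided Fisher's exact test). AAGGCGC was found at 13 of 153, 3 of 96 and 1 of 51 of these summits against 16%, 16% and 15.8% of the others (adjusted p = 0.0117, 0.000226 and 0.00353, two-sided Fisher's exact test). The median signal percentile was 29.1 near tRNA genes, 57.0 near snoRNA genes and 52.6 near snRNA genes. When the list was divided by signal into groups of 325 peaks, GAGACC was found at 16.6% in group 8 from the strongest, which held the median percentile near tRNA genes, at 17.2% in group 7 next to it and at 12.3% in the weakest. No test with matched signal was made. GAGACC and AAGGCGC tended to share peaks, since AAGGCGC was found at 35.1% of summits with GAGACC and 8.31% of those without (two-sided Fisher's exact p = 4.81e-70). GAGACC and GGCGCA, which overlaps AAGGCGC, were both more frequent at stronger peaks. Sharing of the words at matched signal was not tested. A q value above 0.1 was listed for 149 series peaks, of which 131 overlapped a stronger peak, with summits at a median distance of 204 bp from it.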
